A study of Tetrahymena thermophila with 18 samples.

How the data were processed

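RNA was sequenced from the ciliate Tetrahymena thermophila, strain CU428, over a time course of vegetative growth at 30 °C. Cells in G1 were collected by centrifugal elutriation, which sorts cells by size, and returned to a shaken flask. Samples were taken every 30 min from 0 to 240 min, and RNA came from 15 ml of culture per time point. Per the labels' protocols, RNA was purified on columns with DNase digestion and libraries were made from 10 µg of total RNA with an Illumina kit. There were 9 time points with 2 libraries each, which the labels call A and B. The libraries of one letter are called a series here. The labels do not say whether A and B were separate cultures, so p-values measure the spread between these libraries, which may be technical.

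The deposited table held 26259 genes and 18 libraries as estimated counts, whole in the file and not scaled to library size. Per the submitters' processing notes, the authors used Trimmomatic, HISAT2 and StringTie. The versions, the genome build, the annotation and the counting step were not given in the sources used here. In the deposited estimated counts a value of 3 occurred 6575 times, against 1351 times for 1 and 3801 times for 2. Low values therefore did not step by single fragments, and the totals are not taken as numbers of fragments. Strandedness of the counting was not given, so overlapping and antisense genes cannot be told apart, and reads shared by near-identical genes can be split between them.

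The table named genes by a letter and a number and did not pair them with locus tags or descriptions. Of these identifiers, 0 were found in the table of 26996 RefSeq genes used for names. The 29 gene lists fixed before the data were examined (histones, DNA replication, cyclins, kinesins, nuclear pore, ribosomal proteins and others) match descriptions, so none was applied, and the 2 tests planned on them were not run. For that case the rule fixed beforehand was to print 2 identifiers that rose and 2 that fell, without saying how to pick them. They are those with the largest change over the 8 contrasts against 0 min among genes with an adjusted p below 0.05, an average log2 CPM of 3 or more and both later libraries beyond both 0 min libraries. The level and the order of libraries follow the rule set for described genes, and the choice of the largest over the 8 contrasts was made after the identifiers were seen to lack descriptions. All other genes are given as counted groups.

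Genes were kept by edgeR's filterByExpr on the time points, which left 22105 genes. Libraries were scaled by TMM, and values are given as CPM of the scaled library. RNA content per cell was not measured, so every value is relative to the other transcripts. Tests used edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. The main model had the 9 time points and no other term, with 9 residual degrees of freedom, and gave an overall test and 8 contrasts against 0 min. Standard errors of log2 fold changes were taken from the F statistic. Periodic genes were tested in a model with a linear time term and a cosine and sine term of 160 min period, since the series text gives 1.5 cell cycles in 240 min. It had 14 residual degrees of freedom, so its spread also holds the departure of the time points from the fitted curve. Fits of a single series have 1 library per time point, and their p-values rest on that departure only. The tables of log2 CPM used a prior count of 2.

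Whether the letters pair the libraries was checked on the difference between B and A at each time point. These differences correlated across genes between all 36 pairs of time points, with r from 0.175 to 0.671 and a median of 0.496. All lay above 0.1, the threshold used for pairing, so the letters were treated as pairing the libraries. The counts of both fits had already been computed when this was settled, and the fit without the letter stayed the main one, as fixed beforehand. The pairing comes from the values, not from a statement in the labels, and the fit with the letter as a replicate block is given beside the main values where it moves a printed count or fold by over 1.5 times. The biological coefficient of variation was 0.371 without the block and 0.228 with it. Libraries A and B of one time point had different totals, and their chi-square statistic per gene was 111 to 720. That statistic sets them against counting error only, on values that are not numbers of fragments.

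Total counts ranged from 97437187 to 134659286 per library. A count of 3 corresponds to 0.0212 to 0.0351 CPM of the scaled library, which is the floor of detection and covers counting error only.

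The fits were tested on simulated data. Counts were drawn from the real means, dispersions and series differences, with 100 genes changed per fold size. The dispersions came from the fit with the block, and the simulated series difference was constant over time, as the block assumes. In the real data the difference between series changed with time. The values for the block below therefore do not give the error rate of its calls on the real data. For 120 min against 0 min, the main model recovered 2% of the genes changed 2-fold and 50% of those changed 4-fold, with 0 false calls among 21822 genes tested. With the block it recovered 32% and 94%, with 8 false calls. For periodic genes, the main model recovered 31% of those with a peak-to-trough ratio of 2 and 86% of those with a ratio of 4, with 0 false calls, and the block 68% and 96%, with 10. False calls were counted only among genes simulated without a change over time. They do not show how often a change that is not a cycle passes the periodic test.

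Alternatives fixed before the data were examined were median-of-ratios scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-trend (limma 3.58.1), the replicate block, a fold threshold of 2, other periods, a model without the linear term, and each library left out. Other periods of 200, 220 and 240 min, single series, scaling by library totals, and leaving out the 0 min or the 210 and 240 min libraries were added after seeing the data, as were the steps between neighbouring time points and the comparison of late with early time points. DESeq2 gave no adjusted p for 429 genes in the overall test and for 3857 in the periodic test, and these were not counted as lost calls.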

Results

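Transcript levels were followed through the vegetative cell cycle of Tetrahymena thermophila, a ciliate that keeps a germline micronucleus and a somatic macronucleus in a shared cytoplasm, each with its own division schedule. The starting population was a G1 fraction obtained by elutriation, and 9 time points from 0 to 240 min were sampled at 30 min intervals, with 2 libraries per time point (A and B). The series text describes this span as 1.5 cell cycles. Total counts per library ranged from 103964010 to 124803470 in series A and from 97437187 to 134659286 in series B. Between 21852 and 23084 of the 26259 genes had a count in a given library, and 1387 had none in any. The genes are identified by number only, without names or positions, so they are described below in groups defined by their time course.

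The first comparison asked which transcripts changed as the G1 cells moved on. At 30 min, 695 genes were higher and 627 lower than at 0 min, and the median change was 3.12-fold among the higher and 3.24-fold among the lower genes. The number of changed genes grew to 2688 at 60 min, 3473 at 90 min and 4083 at 120 min. It was largest at 150 min, when 2807 genes were higher by a median of 4.2-fold and 1608 were lower by a median of 2.53-fold. It then fell to 4057 at 180 min, 3013 at 210 min and 2266 at 240 min, of which 1601 were higher and 665 lower. The share of changed genes that were higher than at 0 min was 52.6% at 30 min, 63.6% at 150 min and 70.7% at 240 min. With scaling by library totals, chosen after seeing the data, it was 67.9% at 150 min and 61.9% at 240 min. With median-of-ratios scaling it was 61.2% and 67.7%. The rise of the share after 150 min was thus seen with 2 scalings and not with library totals, so it depended on the scaling. All calls are from edgeR's quasi-likelihood test with an adjusted p below 0.05 among 22105 genes. With the series as a block, the same contrasts called 3446, 5673, 6590, 7346, 7600, 7634, 7082 and 5651 genes from 30 to 240 min, and the share that was higher at 180 min moved from 67.4% to 54.9%. Their higher and lower genes numbered 1844 and 1602 at 30 min, 4204 and 3396 at 150 min, and 3434 and 2217 at 240 min. These counts rested heavily on library B of 0 min: without it they were 176, 546, 1310, 2055, 2348, 2155, 940 and 24 from 30 to 240 min. Without library B of the later time point they were 236, 867, 1510, 1785, 2229, 1919, 1687 and 1038, and without library A they moved by over 1.5 times at 30 min (831), 60 min (1514), 210 min (897) and 240 min (475). The split turned toward lower genes at 30 min (616 higher and 922 lower) and 60 min (1201 and 1419) without library A of 0 min, and at 30 min (75 and 101) and 240 min (10 and 14) without library B of 0 min. Without library A of 0 min, higher genes still led at 210 min (1409 and 970) and 240 min (927 and 813).

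**Figure D1:**
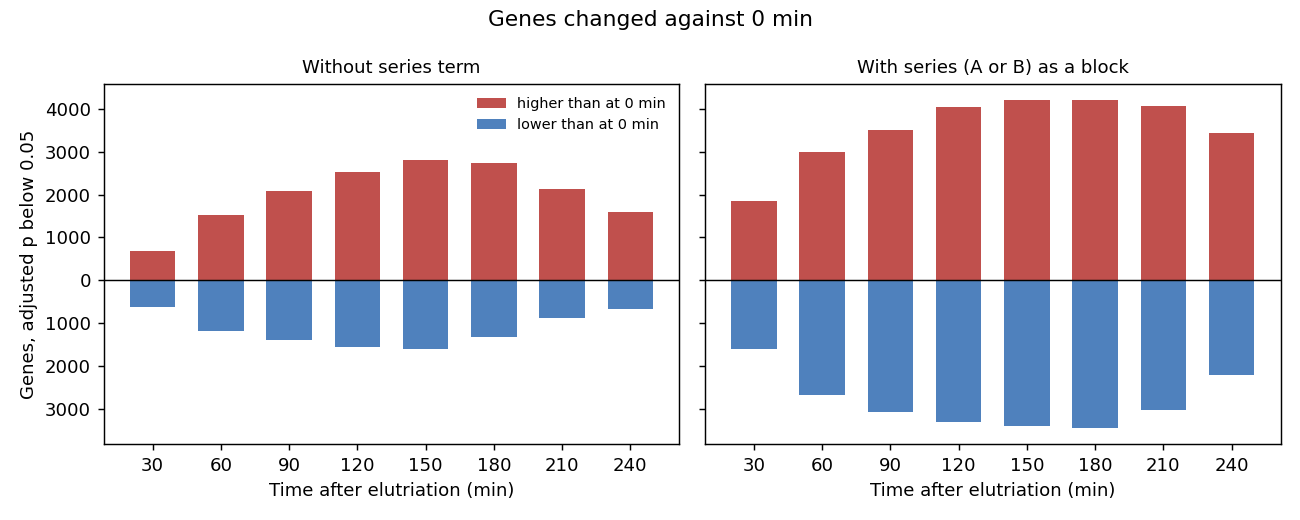
Number of genes (vertical axis) with an adjusted p below 0.05 against 0 min at each later time point (horizontal axis, min), above the line for higher and below it for lower genes, without a series term (left) and with the series as a block (right). Without the series term the counts rise from 1322 genes at 30 min to 4415 at 150 min and fall to 2266 at 240 min.

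The largest rises belonged to transcripts that were nearly absent from the G1 cells and passed through a maximum. Gene g527 was at 0.322 ± 0.355 CPM at 0 min and 63.3 ± 38.3 CPM at 150 min (SD, n = 2), a log2 fold change of 7.59 (SE 0.989, edgeR adjusted p = 0.00041). At 240 min it was lower, at 14.6 ± 4.48 CPM, but still above its 0 min level in both series. Gene g14347 went from 0.822 ± 0.824 CPM to 135.3 ± 54.8 CPM at 180 min, a log2 fold change of 7.35 (SE 0.986, edgeR adjusted p = 0.000634). Both genes had their highest value earlier in series B (150 min) than in series A (180 min). The largest falls belonged to transcripts that were highest at 0 min in both series. Gene g15418 was at 26.3 CPM in library A and 872.5 CPM in library B of 0 min, at 9.2 and 48.7 CPM at 30 min, and at 2.15 and 0.371 CPM at 180 min, a log2 fold change of -8.47 (SE 1.95, edgeR adjusted p = 0.00979). With the series as a block its log2 fold change was -9.09 (edgeR adjusted p = 0.00315). Gene g9378 was at 33.8 and 359.3 CPM at 0 min and at 1.325 and 0.426 CPM at 150 min, a log2 fold change of -7.80 (SE 1.42, edgeR adjusted p = 0.00214). The fall of g15418 lost its call without library B of 0 min (log2 fold change -4.38, edgeR adjusted p = 0.0856) and without library B of 180 min (log2 fold change -7.70, edgeR adjusted p = 0.102), while the other 3 changes kept theirs whichever library was left out. Their log2 fold changes still moved with the 0 min libraries, to 9.85, 9.22 and -8.61 for g527, g14347 and g9378 without library A, and to 6.79, 6.59 and -5.26 without library B. The libraries of the later time points moved them as well. Without library A of 150 min g527 was at 8.09 and g9378 at -8.86, and without library B of 150 min they were at 6.79 and -7.21. The fall of g15418 was -9.36 without library A of 0 min and -10.16 without library A of 180 min.

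**Figure D2:**
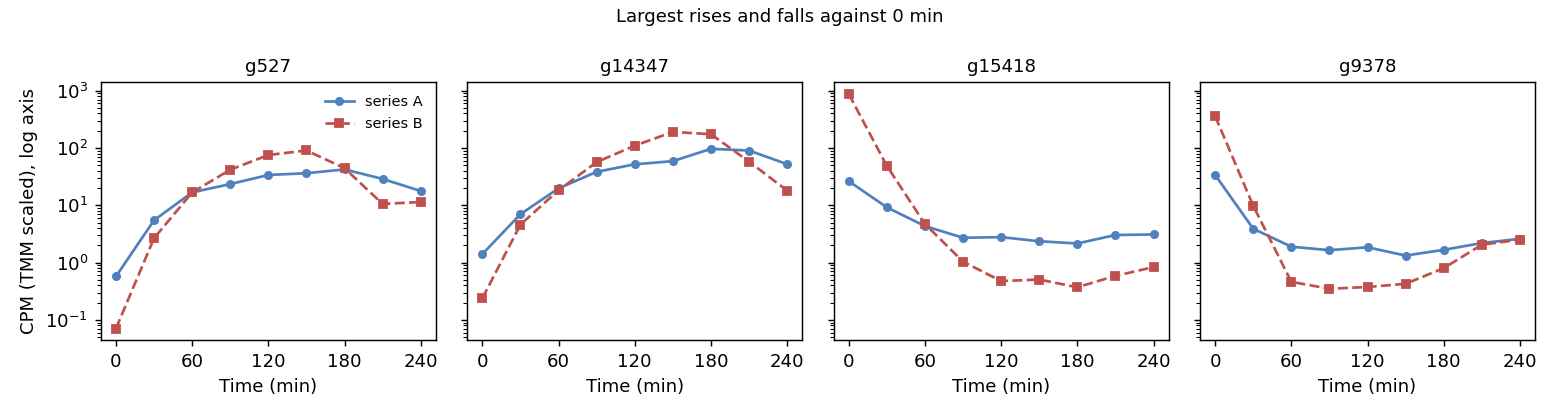
CPM on a log axis against time after elutriation (min) for the 2 identifiers with the largest rise and the 2 with the largest fall against 0 min, one point per library, with series A as circles and series B as squares. g527 and g14347 rise to a maximum at 150 or 180 min and decline, and g15418 and g9378 drop from their 0 min level by 60 min in both series.

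Over all 9 time points, 4249 genes (19.2% of those tested) changed with time (edgeR quasi-likelihood test, adjusted p below 0.05), and 9740 (44.1%) did so with the series as a block, all of the former among them. Most of the 4249 genes had their maximum either in the starting G1 cells or at 150 to 180 min. The mean was highest at 0 min for 963 genes, at 150 min for 770 and at 180 min for 962. Each time point in between held fewer maxima: 357 at 30 min, 257 at 60 min, 93 at 90 min and 386 at 120 min. After 180 min, 336 genes had it at 210 min and 125 at 240 min. The minimum fell at 0 min for 1987 genes (46.8%). In the genes highest at 150 min, the median ratio of the highest to the lowest mean was 6.19-fold, and 86.5% of them were lowest at 0 min. In those highest at 60 min the ratio was 3.35-fold, and 51% were lowest at 0 min. Among the 9740 genes called with the series as a block, the groups highest from 0 to 240 min held 2449, 1126, 745, 348, 821, 1489, 1402, 809 and 551 genes. In that set the genes highest at 150 min had a ratio of 3.39-fold and 64.5% of them were lowest at 0 min, those highest at 60 min had 2.44-fold and 41.1%, and 3368 genes (34.6%) were lowest at 0 min. The time of the maximum was within 30 min in both series for 94.9% of the genes highest at 150 min, 98.1% of those highest at 180 min and 64.8% of those highest at 240 min. The genes were called from both series and grouped by the mean of the same series, so such agreement is partly built in. Without the 0 min libraries, 2093 genes changed with time.

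**Figure D3:**
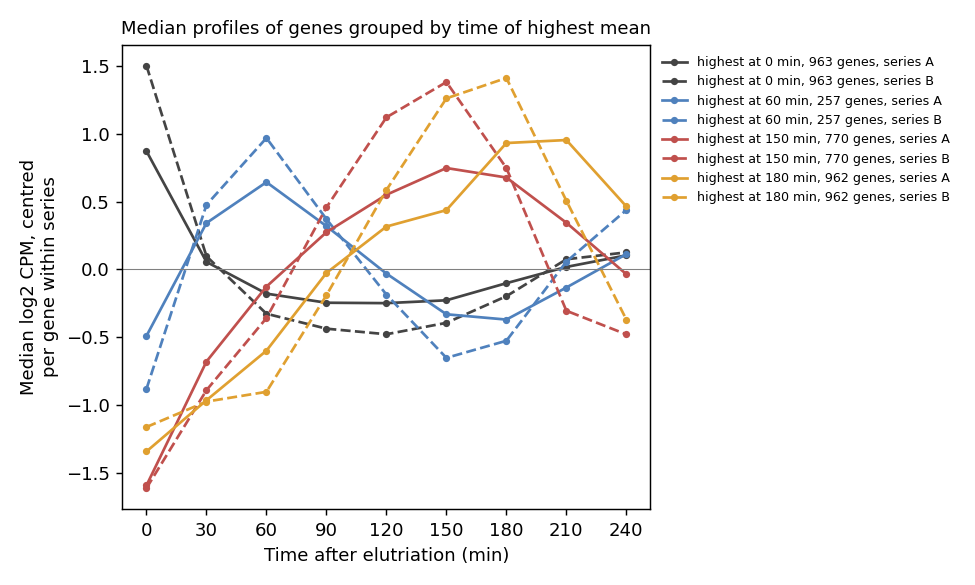
Median log2 CPM, centred per gene within each series, against time after elutriation (min) for genes grouped by the time of their highest mean (0, 60, 150 and 180 min), series A solid and series B dashed. From 180 to 240 min the group highest at 60 min goes from -0.369 to 0.113 in series A and from -0.525 to 0.438 in series B, where its lowest value after 60 min is at 150 min (-0.651), and the group highest at 180 min goes from 0.931 to 0.464 in series A and from 1.41 to -0.369 in series B.

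Because the course was meant to run past a full cycle, the last time points can be compared with the first ones. This comparison was chosen after seeing the data. The 4249 genes, called from both series together, were grouped by the time of their maximum between 0 and 150 min in one series and followed in the other. The 253 genes highest at 60 min in series A had a median centred level of 0.967 (log2) at 60 min in series B, of -0.513 at 180 min and of 0.446 at 240 min. Of these genes 90.9% were higher at 240 than at 180 min in series B, against 38.3% of all 4249. In the reverse direction, the 281 genes highest at 60 min in series B had a median of 0.621 at 60 min in series A, of -0.356 at 180 min and of 0.122 at 240 min, and 87.9% were higher at 240 than at 180 min, against 41.1% of all. The genes highest at 30 min in one series also were mostly higher at 240 than at 180 min in the other: 82.9% of 480 genes in series B and 81% of 415 genes in series A. Of the genes highest at 0 min, 62.2% of 1147 in series B and 75.5% of 1156 in series A were higher at 240 than at 180 min, and the groups stayed far below their starting level. Their median was 1.24 at 0 min and 0.189 at 240 min in series B and 0.75 and 0.188 in series A. Of the genes highest at 90 min, 70.6% of 102 in series B and 53.4% of 133 in series A were higher at 240 than at 180 min. The genes highest at 120 or 150 min went the other way. Of those highest at 120 min, 19.9% of 669 genes in series B and 4.25% of 424 genes in series A were higher at 240 than at 180 min, and of those highest at 150 min, 4.94% of 1598 genes in series B and 10.9% of 1840 genes in series A. Each value rests on 1 library per time point, and genes are not independent replicates, so these shares carry no p-value.

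The next comparison asked which transcripts followed a cycle of 160 min, the period that 1.5 cycles in 240 min imply. With that period 300 genes (1.36% of those tested) passed edgeR's quasi-likelihood test, and 3762 had an unadjusted p below 0.05. Of 30 orders of the time points, the true one included, 10 gave at least 300 genes, with 3416 the highest of the others. Of the 300 genes, 134 had their fitted peak between 64 and 96 min, with a median peak-to-trough ratio of 2.61-fold, and 93 between 32 and 64 min, with a ratio of 3.54-fold. Another 45 peaked before 32 min, 9 between 96 and 128 min, and 19 between 128 and 160 min. With the series as a block 1786 genes passed, of which 250, 398, 503, 138 and 497 peaked in the same windows from 0 to 160 min, and the median ratio of those between 32 and 64 min was 1.8-fold. Without the 0 min libraries 2146 genes passed, 299 of the 300 among them. Of the 2146 genes, 974 peaked between 128 and 160 min, and the median ratio between 32 and 64 min was 1.9-fold. The count depended on the period: it was 0 at 140 min (1330 at an unadjusted p below 0.05), 3943 at 180 min, 6379 at 200 min, 7239 at 220 min and 7584 at 240 min (edgeR, 18 libraries). It was highest at 240 min, the length of the course, so it singles out no period. Series A alone gave 0 genes (edgeR, 2517 at an unadjusted p below 0.05) and series B alone 13 at 160 min, against 3495 and 6854 at 200 min. At 240 min series A alone gave 7048 genes and series B alone 9156. At 160 min the count was also lower by more than 1.5 times when single libraries were left out, to 125 without B at 60 min, 173 without B at 90 min, 199 and 165 without A or B at 120 min, 150 without B at 150 min, 178 without B at 180 min and 173 without B at 210 min.

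**Figure D4:**
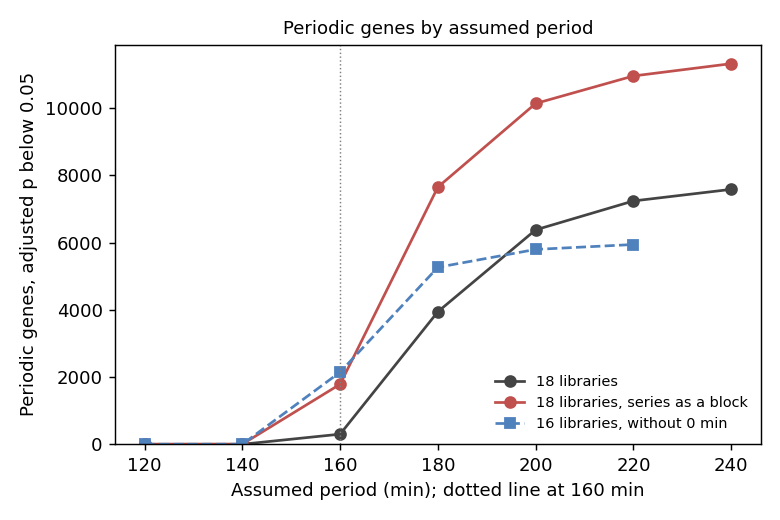
Number of periodic genes (adjusted p below 0.05) against the assumed period (min) for all 18 libraries, for all 18 with the series as a block, and for the 16 libraries without 0 min. All 3 curves lie higher at 180 and 200 min than at 160 min, where they read 300, 1786 and 2146 genes.

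Finally, the 18 libraries were compared with each other on log2 CPM centred per gene within each series, by Pearson correlation across genes, which are not independent replicates. In each of the 9 libraries of series A and each of the 9 of series B, the most similar library of the same series was the one before or after it in time. Between the series, the A libraries of 0, 30, 60, 90 and 120 min were most similar to the B library of their own time, with r from 0.328 at 90 min to 0.763 at 0 min. The later A libraries were most similar to the B library taken 30 min earlier. For 150 and 180 min the margin was small (0.476 against 0.469, and 0.574 against 0.567). For 210 min r was 0.496 with B at 180 min and 0.32 with B at 210 min, and for 240 min it was 0.339 with B at 210 min and 0.114 with B at 240 min. These 4 matches rested on few libraries: without A at 210 or 240 min only 1 A library was most similar to an earlier B library, and without A at 180 min or B at 90 or 120 min 2 were. Without A at 240 min, 7 of the 8 remaining A libraries were most similar to B at their own time. The 0 min library of series A was least like series B at 150 min (r = -0.601) and was positively correlated with it again at 240 min (r = 0.197). The 0 min library of series B correlated with series A at -0.391 at 120 min, -0.328 at 150 min and -0.118 at 240 min.

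**Figure D5:**
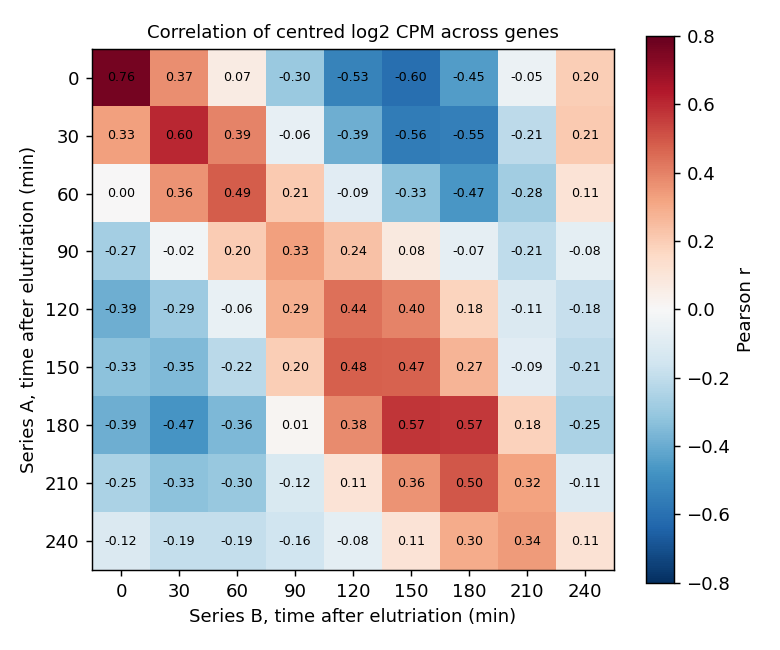
Pearson r across genes between each series A library (vertical axis, min after elutriation) and each series B library (horizontal axis, min), on log2 CPM centred per gene within series. The highest value for each A library lies at equal times up to 120 min and 30 min earlier in series B from 150 min on.

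The 2 series also differed from each other. With time in the model, 4600 genes were higher in series B and 6027 higher in series A (edgeR quasi-likelihood test, adjusted p below 0.05), 48.1% of those tested. There is 1 series per letter, and libraries of one letter deviate together. The test treats them as replicates, so these calls describe these 2 series and not a difference beyond the spread between preparations. Among the 4249 genes grouped by the time of their highest mean, the median centred level at that time was lower in series A in every group. It was 0.747 (log2) in series A and 1.38 in series B for the group of 150 min, and 0.537 and 0.718 for that of 240 min. The 100 most abundant genes of a library took 26.25% to 31.15% of its counts in series A and 31.28% to 33.08% in series B. Over all time points, genes with few counts were the ones higher in series A: the median difference of A minus B was 0.403 (log2) in the lowest of 5 equal groups of genes by level and -0.22 in the highest. The excess of the lowest over the middle group was 0.59 at 150 min, 0.02 at 210 min and -0.0321 at 240 min.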

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

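Scaling by library totals, periods of 200, 220 and 240 min, single series, the tests without the 0 min or the 210 and 240 min libraries, and single libraries left out for similarity were chosen after seeing the data. The replicate block raised the genes changing with time from 4249 to 9740, those changed from 30 to 240 min against 0 min to 3446, 5673, 6590, 7346, 7600, 7634, 7082 and 5651, and the periodic genes from 300 to 1786, and its own construction, which removes the difference between series from the spread, shows the cause. DESeq2 called 7744 genes changing with time, 2483 at 30 min, 4062 at 60 min, 3625 at 240 min and 1628 periodic genes, and its other totals stayed within 1.5 times, while its genes lower than at 0 min from 90 to 210 min (2190, 2470, 2461, 2211 and 1790) did not; the cause was not tested. Scaling by median-of-ratios or by library totals, no filter and limma-trend left every count they were run on within 1.5 times. The stricter filter moved only the periodic genes (456), and a fold or peak-to-trough threshold of 2 moved none. Scaling by library totals moved the median change of all genes at 210 min to -0.336 (log2), against -0.115 with TMM, and the share of higher genes by less than 10 percentage points. From 150 to 240 min that share went from 67.9% to 61.9% with library totals, against 63.6% to 70.7% with TMM and 61.2% to 67.7% with median-of-ratios. Periodic genes numbered 0 at 140 min (edgeR, 1330 at an unadjusted p below 0.05), 92 at 150 min, 3943 at 180 min, 6379 at 200 min, 7239 at 220 min, 7584 at 240 min, 10139 at 200 min with the replicate block, and 138 without the linear term. Series A alone gave 0 (edgeR, 2517 at an unadjusted p below 0.05) and series B alone 13, with fewer libraries. Without the 0 min libraries the genes changing with time fell to 2093 and the periodic genes rose to 2146, and without the 210 and 240 min libraries the genes changed at 30 min fell to 858 and those lower than at 0 min from 30 to 180 min to 334, 699, 887, 973, 1039 and 786. With single libraries left out, where the remaining library of that time is assumed to vary like the rest, the counts against 0 min ranged from 176 to 1538 at 30 min, 546 to 2736 at 60 min, 1310 to 3564 at 90 min, 1785 to 4209 at 120 min, 2229 to 4359 at 150 min, 1919 to 4185 at 180 min, 897 to 3230 at 210 min and 24 to 2428 at 240 min, and the periodic genes from 125 to 437. The genes changing with time (2867 to 4255) stayed within 1.5 times. The 4 named genes kept their direction under every alternative run, and only g15418 lost its call, without library B of 0 min (log2 fold change -4.38) and without library B of 180 min (-7.70). Of the 9 A libraries, 5 were most similar to B at their own time. With single libraries left out this was lowest at 4 (of 9 without B at 0 min, and of 8 without A at 30, 60, 90 or 120 min) and highest at 7 of 8 without A at 240 min. With 2 libraries per time point, simulated 2-fold changes at 120 min were recovered in 2% of genes by the main model, so genes not called are not shown to be constant. The 2 planned tests on gene lists were not run, since 0 identifiers matched a description.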

Other observations

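Tests on the 0 min libraries, on the shift between series and on recurrence between series were chosen after seeing the similarity values, and the order tests, the tests on low-count genes and the shuffles of identifiers before their results were seen; the steps between neighbouring time points were also chosen after seeing the data. Between neighbouring time points, the step from 0 to 30 min stood apart: it changed 1322 genes, while each of the 7 later steps changed at most 1 (edgeR quasi-likelihood test, adjusted p below 0.05). At an unadjusted p below 0.05 the contrast was smaller, with 4152 genes in the first step and 114 to 1118 in the later ones. With the series as a block the first step changed 3446 genes and the later ones again at most 1, with 6420 and 346 to 2286 genes at an unadjusted p below 0.05.

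Genes with consecutive identifier numbers had more similar time courses than other genes. The median correlation between the profile of a gene in one series and that of the next number in the other was 0.0723 over 19376 pairs, above the highest of 1000 shuffles (0.0128; permutation p = 0.001, the smallest they can give). It was 0.0346 at a distance of 2 numbers, 0.0129 at 3 and 0.00497 at 10, and 15.3% of consecutive pairs were above 0.5 against 10.7% at a distance of 50. For scale, the median correlation of a gene with itself between series was 0.613. Whether numbers follow the genome, and whether neighbours share reads, was not tested, since no coordinates were used.

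The 0 min libraries set many of the calls, and a candidate explanation is a passing response to elutriation. Unusual depth is argued against, since 0 of the 2 libraries had a total count outside the range of the other 16, although library A had the most detected genes of all (23084) and library B the most of its series (22675). A return of the 0 min profile every 160 min is argued against by the mean correlation between series of 0 min with 150 and 180 min, which was -0.441. If the 0 min libraries hold a passing response, this value cannot decide whether G1 itself returned. A passing response and a cycle longer than the course cannot be told apart, since no sample without elutriation was analysed here and the mean correlation of 0 min with 240 min was 0.0396. In the order test, 10 of 30 orders of the time points gave at least the 300 periodic genes of the true order (highest other 3416), so chance order is not excluded for that count. The orders with many more genes point to a structure of the libraries such as the separate 0 min point. Without 0 min only the true order gave as many as 2146 genes (1 of 30, highest other 1109). That argues against a chance order, although 30 orders can give no share below 1 of 30. It does not separate a cycle from another smooth course. Both order tests used the fit without the series term, and none was run with the series as a block.

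Late A libraries resembled earlier B libraries, and slower progress of series A may account for it. The best whole-interval shift was 0 min over 0 to 120 min (mean r 0.524) and 30 min over 120 to 240 min (mean r 0.434, against 0.382 without a shift), a difference of 30 min, and a grid of 5 min with interpolated B values, tried first, gave -10 and 15 min, a difference of 25 min. The difference was 30 min in 16 of the 18 fits with a library left out and 0 min without the 240 min library of either series. Without B at 240 min the shifts were averaged over unlike pairs. The mean without a shift lost the pair at 240 min (r = 0.114), while that at 30 min kept all its pairs, so this fit decides nothing. The fit without A at 240 min still leaves a fixed difference in sampling time, slower progress of series A and the 240 min libraries themselves impossible to tell apart. Libraries far out of order within a series are argued against, since 18 of 18 libraries had a neighbouring time as the most similar. This count cannot decide on an exchange of 2 neighbouring libraries. Those of series A at 120 and 150 min were each most similar to the other (r = 0.385), and exchanging them would leave the count at 18. A 200 min period fitted to each series, which gives 1 shift for the whole course, put the peak a median of 4.82 min later in A (quartiles -2.43 to 12.7 min, later in 67.7%) over the 2183 genes called in both series.

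Low-count genes were higher in series A, by 0.337 (log2) in the lowest of 5 equal groups by level relative to the middle one (SE 0.0618 over 9 time points). The SEs here cover the spread over time points of 1 series per letter, not that between preparations. Depth is argued against, since thinning every library to the smallest total left 0.328 (SE 0.0623; the bound of 2 SE was added after the values were seen). Without the top 100 genes 0.343 (SE 0.0626) was left, which decides nothing about a few abundant genes taking more of series B, since leaving genes out rescales the others alike. Of 2012 genes at 0 in every B library, 2.53% had a count in 5 or more of the 9 A libraries. In the reverse direction it was 0.596% of 1677 genes. These shares do not decide on an even background over silent genes in A. Of the 2012 genes, 1387 had no count in any of the 18 libraries, and whether such genes can be counted at all was not tested. The gap was 0.59 at 150 min, 0.02 at 210 min and -0.0321 at 240 min, so it was not a constant of the series, and a difference in culture or library preparation, on which the labels give nothing, could remain behind it.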
